A study of Homo sapiens with 2 samples.

How the data were processed

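Small RNAs of HepG2, a human hepatocellular carcinoma cell line, were profiled on microarrays that carry probes for miRNAs and a few other small RNAs. Per the labels, 1 array held RNA of control cells and 1 array held RNA of cells exposed to TCDD at 10 nM for 48 h. Per the labels' protocols, total RNA was labelled by ligating a dye-bearing RNA linker, and the labels give Cy3 for both arrays. The arrays were hybridised in 2 colours, but per the series' design text the other channel held unrelated samples and the channels were not compared, so each value comes from a single channel.

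The deposited table holds log2 fluorescence values, 1 per probe and array, for 719 probes. The scanner, the background correction and the method of scaling are not given in the sources used here. The smallest deposited log2 value was 5.64 on both arrays, which is a fluorescence of 50. It was shared by 343 of 718 probe names on the control array and by 257 on the array labelled TCDD, so lower values had been raised to it. The remaining values carried a trace of further processing. On the linear scale they lay on a grid of single units bent by a smooth curve, and a second-degree polynomial of log2 signal (exponent 2) reproduced 96.8% of the 375 values above the smallest on the control array and 100.0% of the 461 on the other array to within 0.05 units. The fitted curve multiplied a signal of 100 by 0.994 on the control array and by 1.01 on the array labelled TCDD, and a signal of 10000 by 0.959 and 1.05. The grid was read from the values, and no source used here states the step. On the control array the grid lay 0.833 units off whole numbers, and on the other array the offset was 0.

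Probe names were taken from the table, and the trailing probe number was removed. The 2 probes named miR-340 were averaged on the log2 scale, which left 718 names, of which 670 were human miRNA names and 48 were other small RNAs, unnamed candidates or probes marked as ambiguous. The names are those of the array's design and are old in part (miR-122a, miR-17-5p, star names for the opposite hairpin arm). No genome sequence was given. Pairs of neighbouring miRNA genes were found by matching detected miRNA names (161 matched) to gene symbols of the GRCh38.p14 gene table and comparing gene starts there, and no coordinates are reported.

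With 1 array per group there is no replicate spread, so no test, p-value, standard error or mean with SD was computed, and the number of arrays limits the precision. Nothing in the labels says whether the RNAs came from separate cultures. The rules below were fixed before the data were examined. The floor of each array was set at 2 times its shared smallest value, a fluorescence of 100 (6.64 on the log2 scale). Values under the floor were set to the floor before the log2 difference (array labelled TCDD minus control) was taken, so a fold against an array under the floor is a lower bound and is written "at least". A probe counted as detected if it lay above the floor on at least 1 array, and as changed in size if the arrays were at least 2-fold apart. The miRNAs named in the text are the 12 largest differences in each direction among those at least 2-fold apart, the 5 brightest probes, miR-191, miR-122a, and from each list the 2 highest and 2 lowest detected differences, or all detected members of lists with at most 6 names. Other names were chosen after their values were seen and are said to be so.

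A total of 22 lists of miRNAs (families, genomic clusters, liver miRNAs, miRNAs often raised in liver cancer, and miRNAs of other cell types) was written before the data were examined. Of their 229 names, 184 matched a name on the array exactly. For the 14 lists with at least 3 detected members, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from the detected miRNAs and matched on mean level in 10 bins. This percentile describes the pair of arrays, and miRNAs are not replicates. Alternatives were median centring, quantile normalization, removal of a lowess trend on mean level (fraction 0.5), no floor, a floor at the 75th percentile, adding the floor before log2, thresholds of 1.5-fold and 3-fold, and human miRNA names alone. Recovery of the values before the authors' scaling, by inverting the fitted curve, a match through 9 older names, and list percentiles under each setting that keeps a floor were added after the data were seen. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

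The procedures were tested on simulated data built on the 718 names of this comparison. All of 40 probes simulated at a 4-fold change (100% of them) were called at 2-fold, with an SD of 0.2 for unchanged differences. A 4-fold change lies far past the threshold, and the robust SD on the real arrays was larger, 0.28. This result therefore checks the code and says nothing of calls near 2-fold or near the floor. Of random lists of 10 members, 5% fell outside the central 95%, and 85% of such lists shifted by 0.3 were found above the 97.5th percentile. Smaller lists and lists of near-identical sequences were not simulated. The curve fit returned simulated signals on the unit grid for 100% of values, but these were made with the same kind of curve that was fitted.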

Results

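The series asked how TCDD (tetrachlorodibenzo-p-dioxin, a dioxin that activates the aryl hydrocarbon receptor) affects small RNAs of the liver cancer line HepG2. It comprised 2 arrays, 1 of control cells and 1 labelled as cells exposed to TCDD at 10 nM for 48 h. On the control array 227 of 718 probe names (31.6%) lay above the floor, and on the array labelled TCDD 237 did (33.0%). A total of 242 names were detected on at least 1 array, 222 of them on both, and 222 of the 242 carried human miRNA names. The arrays ranked the detected probes alike, with a Pearson r of 0.989 and a Spearman rho of 0.976 across probes, which are not replicates.

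The brightest probes were those for miR-107 (15.93 log2 fluorescence in control, 16.02 on the array labelled TCDD), miR-103 (15.90 and 16.02), the ambiguous probe ambi_miR_562 (15.93 in control, a mean of 15.96 over both arrays), the small nucleolar RNA RNU48 (15.58 and 16.02) and miR-191 (15.77 and 14.60). RNU48 and miR-103 shared the highest value of the array labelled TCDD and miR-107 lay about 1 fluorescence unit under it, while on the control array miR-107 had the highest value and ambi_miR_562 lay about 1 unit under it. Signals at the top of the range can be saturated, so no difference is given for RNU48, miR-103, miR-107 and ambi_miR_562. miR-191 lay below the highest value of both arrays, and whether its control signal was compressed was not tested. Other bright probes were those for miR-21 (15.11 and 14.86), widely described as raised in tumours, and miR-23b (14.84 and 14.88). The probe for miR-122a, the main miRNA of hepatocytes, was dim at 7.60 and 7.59. Brightness also depends on the probe, so it does not rank the miRNAs by abundance.

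Most small RNAs differed little between control cells and cells labelled as TCDD-treated, and among the few at least 2-fold lower on the array labelled TCDD were miR-181 products and miR-191. miR-191 was 2.25-fold lower on the array labelled TCDD, a log2 difference of -1.17. All directions here rest on the deposited labels. miR-181a was 2.82-fold lower (13.46 in control, 11.97 on the array labelled TCDD) and miR-181b 2.92-fold lower (12.32 and 10.78). miR-181a*, the opposite arm of a miR-181a hairpin, had 8.89 in control and 5.95 on the array labelled TCDD, where it was under the floor, so it was at least 4.74-fold lower. The unnamed candidate 6_5 was 2.47-fold lower (9.27 and 7.96), and miR-184 was 2.03-fold lower (8.41 and 7.39). With the floor applied, the only probe at least 2-fold higher was that for miR-638, a GC-rich RNA often bright on arrays. It was at 12.97 in control and 14.07 on the array labelled TCDD, a 2.14-fold difference.

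These 7 probes, 1 higher and 6 lower, were all that lay at least 2-fold apart among the 242 detected, with the floor applied. Without a floor the counts were 8 higher and 6 lower. Of the 242, 224 (92.6%) lay within 1.5-fold, and the robust SD of the log2 differences over probes detected on both arrays was 0.28. Of the differences 120 lay above and 122 below 0, with a median of -0.003 (-0.07 before the authors' scaling), a balance that scaling can set. None of them could be tested, because each group had 1 array. The call for miR-638 ended at 0.98 before the authors' scaling and at 0.99 with the level trend removed, and that for miR-184 ended at -0.98 with the stricter floor, -0.95 with the trend removed, -0.94 after quantile normalization and -0.72 with the floor added.

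**Figure D1:**
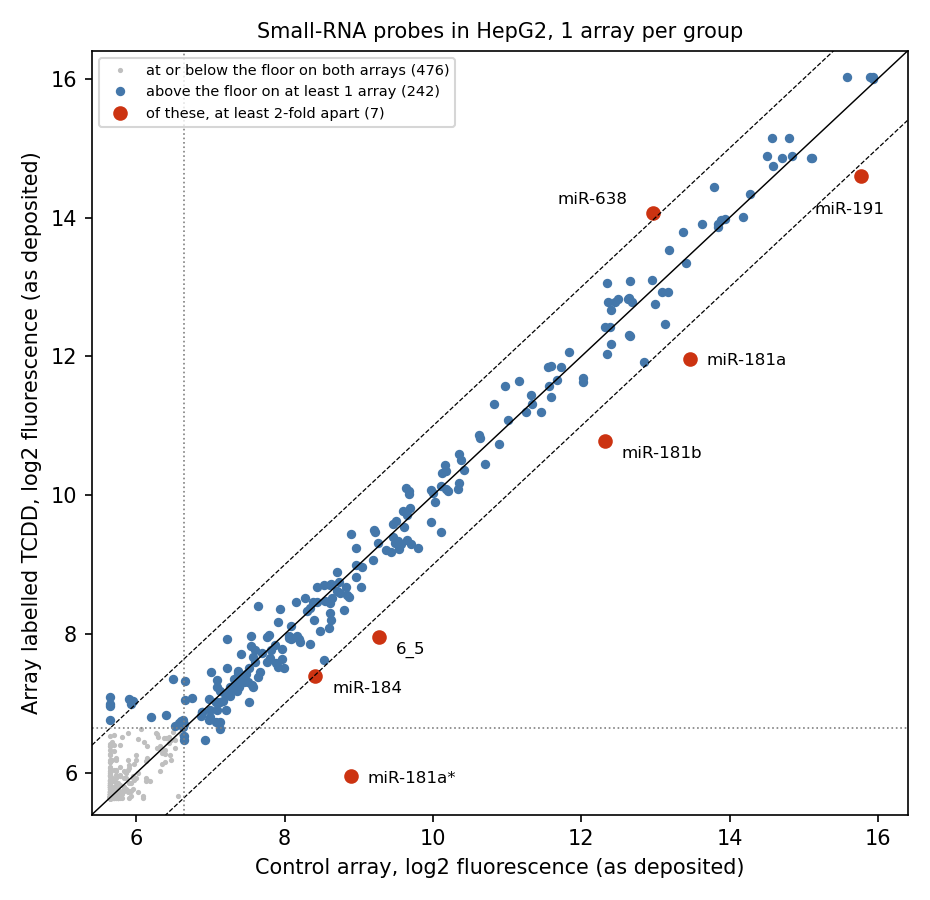
Each point is 1 probe name, with its log2 fluorescence on the control array (x axis) and on the array labelled TCDD (y axis). Dotted lines mark the floor of 6.64, the solid line equality and dashed lines a 2-fold difference; 6 red points lie below the dashed band and 1, miR-638, above it.

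The miR-181 family, a set of miRNAs with a shared seed, had the most extreme percentile of the 14 lists placed among random lists. Of its 4 detected members, 2 (miR-181a and miR-181b) were at least 2-fold lower, none was 2-fold higher, and the list median of -0.98 lay at percentile 0.055 of random lists. miR-181d was at 7.99 in control and 7.51 on the array labelled TCDD, a difference of -0.47. miR-181c had the smallest deposited value in control and lay above the floor on the array labelled TCDD, at least 1.28-fold higher. The miR-181 probes are for near-identical sequences, so the signals of the guide arms are not independent of each other.

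In the cluster of miR-191 and miR-425, whose hairpins lie in one transcript, the neighbours differed less than miR-191. miR-425 was at 12.99 in control and 12.76 on the array labelled TCDD, a difference of -0.23. The opposite arms, named after their values were seen, were at -0.18 for miR-425* and -0.09 for miR-191*. In the cluster of miR-212 and miR-132, reported to respond to the aryl hydrocarbon receptor, miR-132 was near the floor at 6.97 and 6.76, and miR-212 was at or under it on both arrays.

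Members of the proliferation-linked miR-17~92 cluster and its paralogs were mostly a little higher on the array labelled TCDD. Of 11 detected members 10 had differences above 0, all 11 lay within 2-fold, and the list median of 0.28 was at percentile 99.1 of random lists. Before the authors' scaling the median was smaller, 0.17, at percentile 99.3 of random lists drawn from those values. miR-19b differed by 0.60, miR-17-5p by 0.43, miR-25 by 0.12, and miR-92a, the exception, by -0.31 (-0.02 after quantile normalization). The probes of this family also include near-identical sequences. Of the 14 lists placed among random lists, the miR-181 and miR-17~92 lists were the 2 outside the central 95%. Before the authors' scaling all 14 medians moved down, by -0.12 to -0.02, so medians near 0 depend on the scaling, among them those of the miR-200 family (0.03 before scaling), the miRNAs often raised in hepatocellular carcinoma (0.01), the miR-15/16 family (0.008) and the hypoxia and stress list (-0.20).

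The let-7 family, which restrains growth, leaned the other way without standing apart from random lists. Of 8 detected members 7 had differences below 0, with a list median of -0.19 at percentile 13.8. let-7i differed by -0.42 and let-7a by -0.39, while let-7d was at -0.05 and let-7g at 0.02. The miR-30 family had a median of -0.20 over 4 members (percentile 12.2), from miR-30d at -0.36 and miR-30c at -0.24 to miR-30b at -0.15 and miR-30e at 0.08. The miR-23/27/24 clusters had a median of -0.17 over 5 members (percentile 8.14), with miR-27a at -0.26, miR-27b at -0.24, miR-24 at -0.17, miR-23a at 0.03 and miR-23b at 0.04. The miR-29 family had members on both sides, with miR-29b at -0.51, miR-29c at -0.25 and miR-29a at 0.33 (median -0.25, percentile 16.8).

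The list of liver miRNAs had 7 detected members, with a median of 0.07 at percentile 64.5, which turned to -0.05 with the level trend removed. All lay within 2-fold as measured, but miR-103 and miR-107 are among them and may be saturated, which limits the count and the median. miR-194 was the furthest, at 12.34 in control and 13.06 on the array labelled TCDD, a 1.64-fold difference, while miR-192, which is co-transcribed with a miR-194 copy and was named after its value was seen, was at 13.88 and 13.96. miR-215 lay under the floor on the array labelled TCDD and was at least 1.22-fold lower there, and miR-122a had a difference of -0.01. Of 13 detected miRNAs often raised in hepatocellular carcinoma, 8 had differences above 0 and all lay within 2-fold (median 0.12, percentile 78.1). The furthest were miR-106b at 0.34, miR-301a at 0.28, miR-183 at -0.36 and miR-30d at -0.36.

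In the hypoxia and stress list, miR-146a, an inflammation-linked miRNA, was 1.55-fold lower (10.10 in control, 9.47 on the array labelled TCDD), miR-21 differed by -0.25, miR-146b-5p by 0.08, and the hypoxia-linked miR-210 by 0.19 (list median -0.09, percentile 22.2). The epithelial miR-200 family had 3 detected members, with miR-200a at 0.30, miR-200c at 0.13 and miR-200b at 0.07 (percentile 65.2). Of the miR-15/16 family, miR-497 was near the floor with a difference of 0.67 (0.38 with the floor added), miR-15b differed by 0.13 and miR-16 by -0.01 (median 0.13, percentile 63.8). Of the p53-responsive miR-34 family, miR-34a alone was detected, at 14.50 and 14.89.

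Listed members of clusters of embryonic, placental and imprinted miRNAs were largely undetected. Of 40 listed names of the primate-specific chromosome 19 cluster, 26 matched the array exactly, and other probes of the cluster were not counted. Of the 26, 3 were detected, with miR-520a-3p at -0.49, miR-498 at -0.05 and miR-517c at 0.03 (median -0.05, percentile 56.9). Of 38 matched names of the imprinted DLK1-DIO3 cluster, 3 were detected, all near the floor and only on the array labelled TCDD. They were miR-369-3p, miR-370 and miR-382, with bounds of 0.46, 0.32 and 0.17 (percentile 87.3, and 98.0 with the floor added). Detected only there, they could only have differences above 0, so the percentile does not show a rise of the cluster. Of all detected probes, 15 lay above the floor only on that array and 5 only on the control array. Of 9 listed embryonic stem cell cluster members, miR-371-5p differed by -0.19 and miR-372 by 0.05, and the others were undetected. Star arms outside the list, named after their values were seen, were also detected. Among them were miR-373* (8.54 in control, 8.47 on the array labelled TCDD) and miR-302d* (8.21 and 7.89).

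Markers of other cell types were mostly undetected. None of the 7 blood and 4 muscle miRNAs whose listed names matched the array was detected. Of the neural list, miR-138 was at 8.89 in control and 9.44 on the array labelled TCDD, and miR-128, matched through older names after the values were seen, was detected as miR-128a (8.70 and 8.62) and miR-128b (9.19 and 9.07). The fibroblast and smooth muscle miRNAs miR-145 (12.39 and 12.42) and miR-143 (10.17 and 10.36) were present on both arrays. Of 5 detected members of the list of GC-rich RNAs, 2 were higher, miR-638 and miR-663 (1.10 and 0.41). The other members, among them miR-765 (-0.28) and miR-149 (-0.19), were not. The list median was -0.05, at percentile 39.7, and 0.17 under the stricter floor. It does not count miR-149*, the opposite arm of miR-149, which was higher at 0.49 and was named after its value was seen.

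Among other small RNAs, described after their values were seen, the spliceosomal RNU6B was at 13.79 in control and 14.44 on the array labelled TCDD, 1.57-fold higher, and 5S ribosomal RNA was at 14.57 and 15.15, 1.49-fold higher. RNU44 differed by 0.07, RNU24 by 0.03, RNU66 by -0.08 and RNU38B by -0.15. The difference also moved with signal level: over probes detected on both arrays its median was -0.05 in the dimmest of 4 level bins (56 probes), -0.13 in the next, 0.02 in the third and 0.08 in the brightest.

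**Figure D2:**
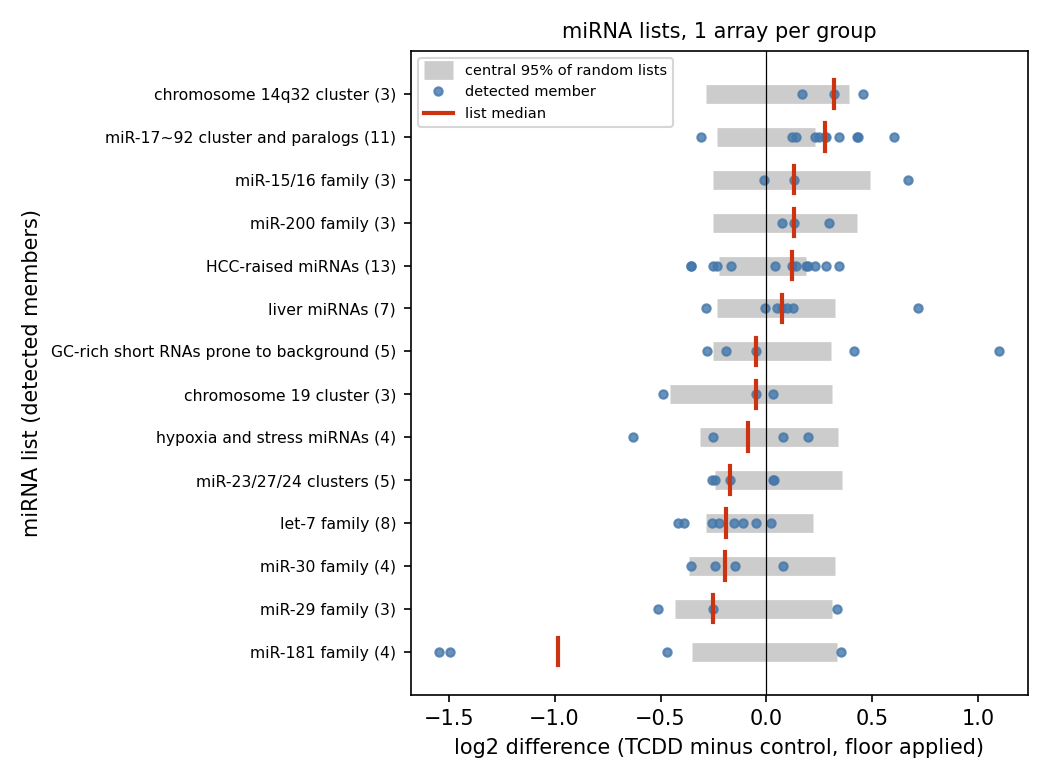
The log2 difference (array labelled TCDD minus control, x axis) is shown for each detected member (points) of the 14 lists with at least 3 detected members, with the list median (red bar) and the central 95% of 10000 level-matched random lists (grey). The miR-181 median of -0.98 and the miR-17~92 median of 0.28 lie outside the grey bars.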

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

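Recovery of the values before scaling, the match through older names and the list percentiles under other settings were chosen after the data were seen. The 7 probes at least 2-fold apart kept 5 of their number under the lowess correction, 6 each under quantile normalization, the stricter floor, the added floor and before scaling, and all 7 under median centring and with no floor. The count higher was 0 with the lowess trend removed, 0 before the authors' scaling, 8 with no floor, 8 at 1.5-fold and 0 at 3-fold. The count lower was 10 at 1.5-fold, 1 at 3-fold and 7 before scaling, where miR-21* joined at -1.05. With no floor, the 7 added probes were all higher on the array labelled TCDD and under the floor on the control array. Their folds rest on dim or clipped control values. The count higher therefore depends on the floor. miR-191 stayed between -1.33 and -1.17, miR-181a between -1.63 and -1.47 and miR-181b between -1.67 and -1.41 under every setting run, while miR-181a* had a bound of -1.46 with the stricter floor and a plain difference of -2.94 with no floor. The miR-181 list median was -1.50 under the stricter floor, which left miR-181c out, and the imprinted DLK1-DIO3 list median was 1.32 with no floor. The other 96 list medians under alternatives moved by at most 0.26, but 12 of the 14 main medians were themselves under the robust SD between single miRNAs, 0.28, so small moves say little, and 27 of the 96 changed sign or moved by over 1.5 times. In all 7 settings with a floor, the miR-181 list stayed between percentiles 0.055 and 0.16 and the miR-17~92 list between 98.3 and 99.4. Of the other lists, only the DLK1-DIO3 list left the central 95% by percentile, in 1 setting. With the floor added it lay at percentile 98.0, though its median of 0.58 only equalled the upper bound of random lists. Only 2 list medians changed sign. That of the liver list was -0.05 with the trend removed, and before scaling it rested on the possibly saturated miR-107, so its sign there is not read. That of the GC-rich list was 0.17 under the stricter floor. Of 453 alternative values for the 66 named probes, 443 moved by less than the robust SD of 0.28, and no 2-fold difference reversed. Several settings barely change probes well above the floor, so this count is in part fixed by construction. Some small differences changed sign between settings, such as those of miR-200b (-0.09 to 0.08), miR-146b-5p (-0.08 to 0.08) and miR-23a (-0.23 to 0.03). The median shift of all detected probes stayed within 0.1 log2 under each scaling, -0.07 before the authors' scaling being the furthest. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Dim probes are limited by the floor: 476 of 718 names lay at or under it on both arrays.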

Other observations

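The tests on miR-191, miR-181 and the miR-17~92 star arms were chosen after their results were seen, while those on the level trend, hairpin arms and neighbouring genes were set before. Further miRNAs, named after their values were seen, lay between 1.5-fold and 2-fold lower. miR-21*, the passenger strand of miR-21, was at 12.84 in control and 11.93 on the array labelled TCDD, a difference of -0.92 (-1.05 before the authors' scaling, past 2-fold), against -0.25 for miR-21. miR-148b (8.53 and 7.62) and miR-193b (13.13 and 12.47) were also lower, with differences of -0.91 and -0.66.

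The lower miR-191 signal is the result a reader would most want to check, because it is among the brightest probes and its direction rests on the labels alone. The fitted scaling curve does not account for it, since the difference with that curve inverted was -1.29. Other processing steps could not be undone. An equal fall of all mature products of miR-191 and miR-425 is argued against by the other 3, whose median was -0.18, although miR-191* lies near the floor. The arrays do not measure the transcript, so an equal fall of the transcript itself was not tested. Exchanged labels stay open: with the labels turned the value would be 1.17 and every other sign would turn too, and no array feature of known direction under TCDD settles it, so this cannot be told apart from a true decrease. Differences between the cultures themselves were not tested.

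The miR-181 decrease involves more than 1 sequence. The median of miR-181a, miR-181b and miR-181a* before scaling was -1.67, which argues against the fitted scaling curve as the source. Whether miR-181b itself was lower stays open: its difference minus that of miR-181a was only -0.051, as both a decrease of each and signal borrowed from miR-181a by cross-hybridisation would give. miR-181a* is the star arm of the miR-181a-1 hairpin and miR-181a-2*, that of the other miR-181a hairpin, differed by -0.32 (9.54 in control, 9.23 on the array labelled TCDD). Since miR-181a* lay under the floor, the gap between the star arms is a bound that depends on the floor, -1.93 or lower with the main floor and -1.14 or lower with the stricter one, and a candidate explanation is a change of the miR-181a-1 and miR-181b-1 hairpins more than of the second pair. It was found on these arrays, rests on 1 pair of probes with 1 of them under the floor, and has the same open question of the labels.

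The miR-17~92 shift was small but shared. With the level trend removed its median was 0.24, at percentile 99.4 of random lists (upper bound 0.21). Random lists were matched on level in the main setting too, so its percentile of 99.1 nearly fixed this outcome. It is therefore not a separate test of the trend. The level-matched lists themselves show only that the list stood higher than miRNAs of like level. Before the authors' scaling it was smaller, 0.17 (upper bound 0.14). Cross-hybridisation among near-identical guide arms stays open: 8 of 9 detected star arms of these hairpins were also higher. Their median of 0.25 only equalled the upper bound of random lists (percentile 97.545). At least miR-19b-1* was under the floor on the control array, so it could only come out above 0, which limits the count. The most divergent were miR-92a-1* at 0.76 and miR-92a-2*, from the paralogous cluster, at -0.15. RNU6B and 5S RNA, at 0.65 and 0.57, were higher on the same array, and whether the small RNA input differed was not tested.

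Of hypotheses set beforehand, 2 were left open. Over 54 pairs of hairpin arms the Spearman correlation of the differences was 0.26, at percentile 97.0 of 10000 shuffles, with the same sign in 31 pairs, and it was 0.18 without the miR-181a pairs. For 64 pairs of neighbouring miRNA genes whose miRNAs have different numbers in their names (within 10 kb in the GRCh38.p14 gene table; some pairs share a family, such as miR-15b and miR-16), the median gap between their differences was 0.25, at percentile 13.9 of level-matched shuffles, with the same sign in 43 pairs. The neighbour pairs were made from 45 miRNAs, so many share a member and the same-sign count is not over separate observations. Both hypotheses went in the predicted direction and neither passed the bound, which does not show that arms or neighbours differ independently.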
